A study of Mus musculus with 6 samples.

How the data were processed

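Total RNA of 6 samples of 3T3-L1 cells, 3 wild type and 3 Ube3d knockout, was depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. The cells had been kept below full confluence and were not differentiated. The authors deposited raw read counts per gene and raw read counts per DoG region for the same libraries. Alignment with STAR 2.6.1d, counting with featureCounts 1.6.3 and the mm10 or GRCm38 mouse genome are named in the submitters' processing notes, with no role per file. How the DoG regions were defined, which strand setting was used for counting and how reads with several alignments were treated are not given in the sources used here. The deposited gene counts are whole numbers and carry the gene symbol, the exon coordinates and the strand. Of 23085 genes found in both, 99.4% overlapped the GRCm38.p6 position of the same symbol in the RefSeq gene table. The deposited DoG counts are whole numbers for 1693 regions in a fixed order, with no name, position or length. Regions are therefore numbered by row. Of these, 7 had no count, and the 6 rows that repeated another row were all among these empty ones.

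Groups and replicate numbers were taken from the sample titles. The titles call the samples biological replicates, and how separate the cultures were is not given in the sources used here. Within-genotype pairs differed by more than sampling noise, with a chi-square per gene between 2.05 and 6.76, so no library was counted as a duplicate. Library sizes were the total gene counts, from 23767181 to 29389480. A gene with no count in a group was set against a floor of 3 counts per library, and a gene with 1 to 3 counts was given a ratio with an exact 95% binomial interval. The gene of the ribosomal RNA precursor, Rn45s, took 9.99% ± 0.28 of the counts in the knockout and 7.99% ± 0.83 in wild type. These counts do not tell precursor from mature ribosomal RNA left after depletion.

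Differences between genotypes were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, robust fitting, TMM scaling and filterByExpr defaults (a minimum count of 10 and a total of 15). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 12947 tested genes, with calls at an adjusted p under 0.05. The SE is the absolute log2 fold change divided by the square root of F. DoG counts were tested in the same way, with the library sizes and TMM factors of the gene counts, since DoG reads are only a part of each library. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Single values per library were compared with a two-sided exact permutation test. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.

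The test, the design, the alternatives, the 34 gene lists and the rule for named genes were chosen before the data were examined. By that rule the genes to name were Ube3d, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM, non-overlapping groups and a regular symbol, up to 4 members of each list with the smallest adjusted p, and the 6 DoG regions with the largest rise and the 6 with the largest fall at a mean count of at least 10. Of the 12 largest rises, 10 are named in the text. Other genes named were chosen after their values were seen. At least 3 tested members were asked of a list, which left out 3 lists: mitochondrially encoded genes (0 genes in the table), epithelial markers (10 genes in the table, 0 tested, highest Cldn7 at 0.295 CPM) and endothelial markers (1 tested, Vwf at 0.778 CPM).

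The gene, DoG and list tests were checked on simulated counts with the means, dispersions and library sizes of these libraries. Of 50 genes each changed by 4 sizes up to 4-fold, 62% of those changed least and 98% of those changed most were called, with 7 false calls among 12947 genes. With a simulated 1.5-fold rise of all 1670 DoG regions the median log2 change was 0.58 and 89.5% were called, and with no change 0% were called. For gene lists, 1 list with a small shift was called and 0 of the other lists, but genes were simulated as independent, so this does not test the list calls under correlation between genes.

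Alternatives were RLE size factors, no count filter and a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, other library sizes for the DoG counts, and each library left out in turn. Leaving out Rn45s, and leaving out the chromosomes with a shifted median, were added after the data were seen. The planned tests of DoG regions against their host genes, of host genes among the called genes and of genes downstream of hosts could not be run, because the DoG regions carry no names.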

Results

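RNA was sequenced from 3T3-L1 cells, a mouse embryonic fibroblast line that is widely used as a preadipocyte model because it can be induced to form fat cells. The cells were undifferentiated and in log-phase growth. Wild-type cells were compared with cells in which Ube3d was knocked out, with 3 libraries per genotype that the sample titles call biological replicates. Ube3d encodes a ubiquitin ligase known as a partner of CPSF73, the endonuclease that cuts pre-mRNA at its 3′ end. The gene counts per library were 23767181, 29389480 and 26862276 in wild type and 25267434, 27214306 and 28042970 in the knockout. Of 24421 listed genes, 6449 had no count in any library and 12947 were tested. Values are mean CPM, that is, counts scaled to library size, ± SD with n = 3 libraries per genotype, and fold changes are knockout over wild type with the SE on the log2 scale, unless stated otherwise.

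Ube3d itself was lower in every knockout library. The gene is listed under its older symbol Ube2cbp, at chromosome 9, 86307234 to 86464916 on the minus strand of GRCm38, with 10 exons. Its level was 1.89 ± 0.31 CPM in the knockout and 6.80 ± 0.80 CPM in wild type, a 3.62-fold decrease (log2 fold change −1.86, SE 0.15, edgeR adjusted p = 7.2e-18). The knockout libraries held 56, 43 and 53 Ube2cbp counts and the wild-type libraries 145, 229 and 173. The counts span the whole gene, and the part removed in the knockout is not given in the sources used here, so the remaining counts cannot be assigned to it.

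**Figure D1:**
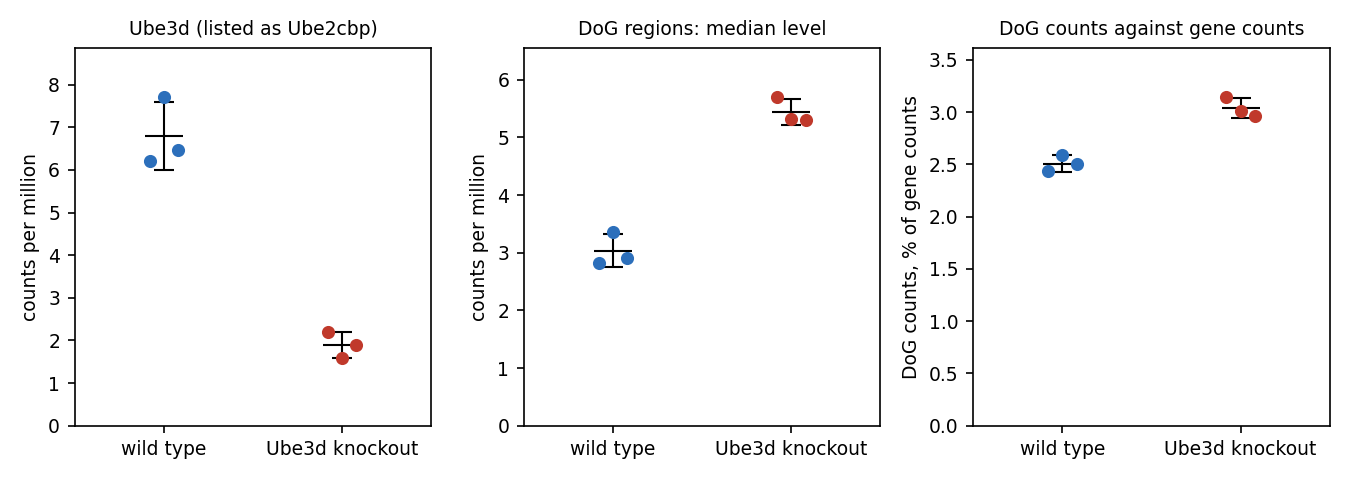
Level of Ube3d (listed as Ube2cbp) in CPM, median level of the downstream-of-gene (DoG) regions in CPM, and DoG counts as a percent of gene counts, in wild-type (blue) and knockout (red) libraries. Points are single libraries, the long bar is the mean and the whiskers the SD of 3 libraries; the Ube2cbp mean is 1.89 in the knockout and 6.80 in wild type, and the median DoG level 5.44 and 3.04.

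The knockout and wild-type transcriptomes differed in 7955 of the 12947 tested genes (61.4%), of which 3918 were higher and 4037 lower in the knockout (edgeR quasi-likelihood test, adjusted p under 0.05). At least a doubling was seen for 573 genes and at least a halving for 424, and with a filter at 1 CPM the doubled genes numbered 348, so that many of them had very low counts. The largest rise among named genes of at least 1 CPM was that of Prkcb, a protein kinase C isoform, at 31.4-fold (log2 4.97, SE 0.31), from 0.131 ± 0.084 to 4.09 ± 0.11 CPM. It was followed by the serine protease gene Klk8 (17.7-fold, SE 0.36), Rnf225 (16.4-fold, SE 0.10), the Wnt ligand Wnt7a (14.6-fold, SE 0.35), the potassium channel gene Kcnt2 (log2 3.81, SE 0.12) and the tubulin gene Tubb4a (log2 3.81, SE 0.26). Klb, the co-receptor of endocrine FGFs, rose 12.3-fold (SE 0.29), the arginine deiminase gene Padi2 by 3.46 on the log2 scale (SE 0.09), Odf3l1 10.9-fold (SE 0.24) and the dynein gene Dnah10 10.6-fold (SE 0.25). The most highly expressed of these in the knockout were Padi2 at 30.5 ± 0.34 CPM and Rnf225 at 29.7 ± 1.7 CPM. The exons of Kcnt2 and Padi2 overlap those of genes on the other strand. Dnah10 starts 0.63 kb downstream of Atp6v0a2 on the same strand.

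Several genes were nearly absent from the knockout. Casc4, Fbln1 (fibulin 1) and Rnf144a had 0 counts in all 3 knockout libraries, against 8.60 ± 1.68, 5.44 ± 0.57 and 2.57 ± 0.45 CPM in wild type. Against a floor of 3 counts per library, they were at least 77.2-fold, at least 48.9-fold and at least 23.1-fold lower. Igfbp3, a binding protein of insulin-like growth factors, had 2 counts in the knockout and 509 in wild type (ratio 0.00388, 95% interval 0.000469 to 0.0141). Etl4 had 1 against 168 counts (ratio 0.00588, 0.000148 to 0.0332), and the scavenger receptor gene Scara5 had 2 against 280 (ratio 0.00706, 0.000850 to 0.0257). Such floors and intervals cover counting error only. The protease inhibitor gene Serpine2 fell 199.7-fold (SE 0.24), Itpripl1 92.6-fold (SE 0.29), the methyltransferase gene Nnmt 79.0-fold (SE 0.23), the metalloprotease gene Adam33 74.8-fold (SE 0.39), the cadherin gene Cdh19 50.4-fold (SE 0.14) and the glypican gene Gpc4 41.3-fold (SE 0.12). Gpc4 went from 34.0 ± 2.7 CPM in wild type to 0.820 ± 0.079 CPM in the knockout.

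Many calls were small. The change was under 0.32 on the log2 scale for 3902 of the 7955 called genes (49.1%), and the biological coefficient of variation was 3.01%. The groups did not overlap for 64.3% of the tested genes, where chance gives 10% for 3 libraries against 3. The first principal component held 83.1% of the variance and separated the genotypes. The sources used here do not say whether the knockout samples came from a single clone, and the p-values measure the spread between these samples only.

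**Figure D2:**
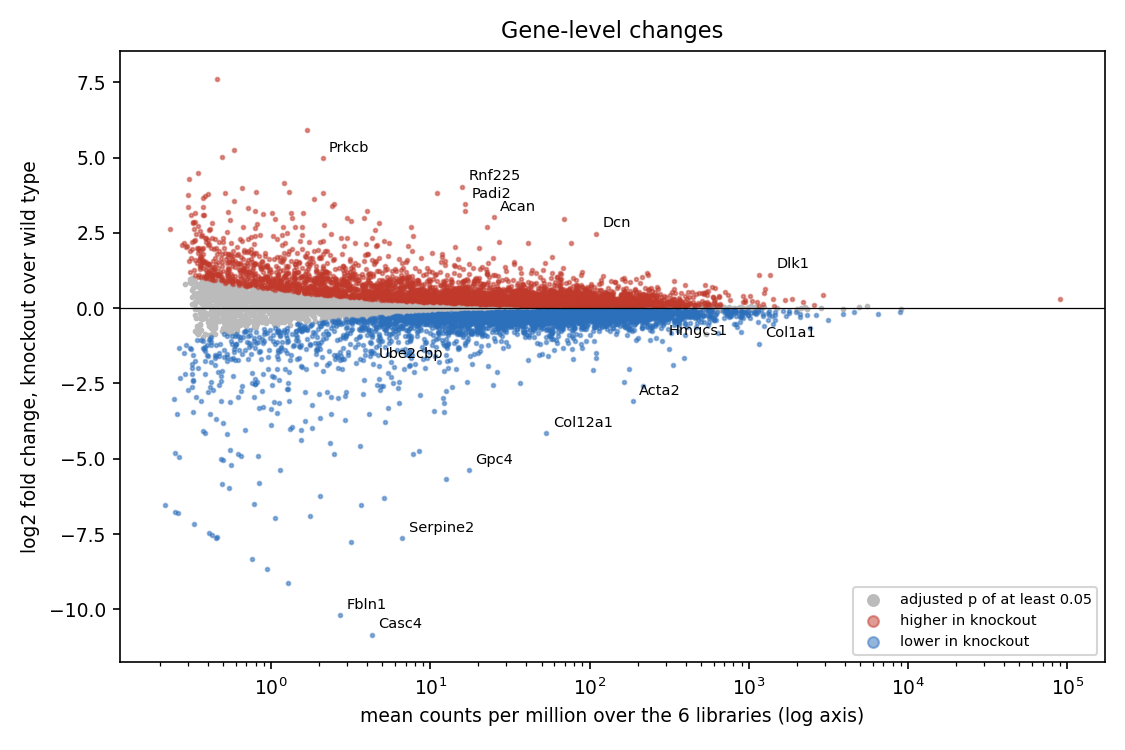
Log2 fold change (knockout over wild type) of the 12947 tested genes against mean CPM over the 6 libraries on a log axis. Red and blue points are the 3918 genes called higher and the 4037 called lower; the fitted change of a gene with 0 counts in the knockout, such as Casc4 or Fbln1, depends on a prior count and is not a bound.

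Genes of the extracellular matrix and the contractile cytoskeleton were lower. Of 21 tested fibrillar collagen and matrix genes, 14 fell and 4 rose (median log2 −0.55). Col12a1 fell 17.7-fold (SE 0.06), from 101.5 ± 4.6 to 5.70 ± 0.32 CPM, the collagen cross-linking enzyme gene Lox 3.72-fold (SE 0.03), the matricellular gene Thbs1 3.17-fold (SE 0.03) and Col1a1 2.27-fold (SE 0.03), from 1603 ± 68 to 707 ± 13 CPM. The camera adjusted p was 6.6e-08, and the adjusted p was 0.155 with an estimated correlation. Of 14 myofibroblast and smooth muscle genes, 12 fell and 2 rose (median −0.57, camera adjusted p = 4.1e-06, and adjusted p = 0.114 with an estimated correlation). Acta2, smooth muscle actin, fell 8.52-fold (SE 0.04), from 333 ± 5.5 to 39.0 ± 2.8 CPM, Tagln 5.53-fold (SE 0.09), Tpm1 1.53-fold (SE 0.03) and Vcl 1.44-fold (SE 0.03). Matrix metalloproteinases and their inhibitors went both ways, with 7 higher and 8 lower of 17 (median −0.14, camera adjusted p = 0.193). Timp3 fell 3.21-fold and the aggrecanase genes Adamts1 and Adamts5 2.55-fold and 3.80-fold, while Timp2 rose 2.15-fold to 1579 ± 15 CPM. Off chromosomes 2, 3, 5 and 12 the list median was −0.25 (camera adjusted p = 0.0997). TGF-beta target genes were also divided, with 8 higher and 5 lower of 14 (median 0.13 but mean −0.45, camera direction higher with adjusted p = 0.738). Tgfbi fell 28.9-fold and Ctgf 5.56-fold, Pmepa1 fell 1.91-fold, and Ltbp2 rose 2.04-fold.

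All 19 tested cholesterol synthesis genes were lower in the knockout, with a median log2 change of −0.90 (camera adjusted p = 6.9e-19). The adjusted p was 0.114 with an estimated correlation. Idi1 fell 2.48-fold (SE 0.04), Nsdhl 2.27-fold (SE 0.04), Hmgcs1, which makes the HMG-CoA of the mevalonate pathway, 2.12-fold (SE 0.03) and Msmo1 2.10-fold (SE 0.03). Hmgcs1 went from 386.5 ± 14.9 to 182 ± 4.6 CPM.

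Markers of the preadipocyte state moved in both directions. Of 17 preadipocyte and mesenchymal progenitor markers, 10 fell and 4 rose (median −0.34, camera adjusted p = 0.040, and adjusted p = 0.197 with an estimated correlation). The fibrillin gene Fbn1 fell 5.99-fold (SE 0.03), Ly6a, which encodes the progenitor antigen Sca-1, 2.22-fold (SE 0.04) and Pdgfrb 1.62-fold (SE 0.03), while the proteoglycan gene Dcn rose 5.57-fold (SE 0.04), from 33.5 ± 1.9 to 186 ± 1.5 CPM. This call was lost without knockout replicate 3 (median −0.38, adjusted p = 0.0502), with a filter at 1 CPM (median −0.28, adjusted p = 0.094) and among the 12 members off chromosomes 2, 3, 5 and 12 (median −0.30, adjusted p = 0.341). Of 19 adipogenic transcription factors, 10 fell and 2 rose, and the list missed the threshold (median −0.20, camera adjusted p = 0.107). Cebpd and Cebpb, which act early in adipogenesis, fell 2.29-fold (SE 0.08) and 1.74-fold (SE 0.05), Ebf1 fell 1.75-fold (SE 0.05), and Klf5 rose 1.40-fold (SE 0.05). The 7 members not past the threshold included Pparg (log2 −0.13, edgeR adjusted p = 0.085) and Cebpa (log2 −0.08, edgeR adjusted p = 0.839). Among 15 tested mature adipocyte and lipid storage genes, 8 fell and 1 rose (median −0.21, camera adjusted p = 0.0080, and adjusted p = 0.170 with an estimated correlation). The list holds 25 genes, and Adipoq, Plin1 and Lep were among those with too few counts to test. The lipase gene Lpl fell 2.49-fold (SE 0.04), Acsl1 1.53-fold (SE 0.06), the desaturase gene Scd1 1.41-fold (SE 0.03) and Acaca 1.27-fold (SE 0.03). Among the 12 members off chromosomes 2, 3, 5 and 12 the median was −0.12 (camera adjusted p = 0.022). Inhibitors of adipogenesis had 7 members higher and 5 lower of 17 (median 0.09, camera adjusted p = 0.418). Dlk1, the preadipocyte factor Pref-1, rose 2.17-fold (SE 0.03) to 1869 ± 56 CPM, Id2 1.55-fold and Sox9 1.31-fold, and Klf2 fell 2.09-fold.

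The osteoblast and chondrocyte genes that could be tested were mostly higher, with 7 of 9 rising and 0 falling (median 0.60, camera adjusted p = 1.4e-04, and adjusted p = 0.155 with an estimated correlation). The list holds 20 genes, and Sp7, Alpl, Bglap and Col2a1 were among those with too few counts to test. Acan, the cartilage proteoglycan aggrecan, rose 8.12-fold (SE 0.07), from 5.50 ± 0.30 to 44.6 ± 0.52 CPM, Sox5 2.42-fold (SE 0.05), Spp1, osteopontin, 1.71-fold (SE 0.03) and Sox9 1.31-fold (SE 0.03). Of the 7 that rose, 2 lie on chromosomes 3 and 5, and off chromosomes 2, 3, 5 and 12 the median was 0.39 (camera adjusted p = 6.1e-04). Of 18 p53 target genes, 9 rose and 3 fell (median 0.15, camera adjusted p = 0.016, and adjusted p = 0.207 with an estimated correlation). The CDK inhibitor gene Cdkn1a rose 2.26-fold (SE 0.04), Zmat3 1.97-fold (SE 0.03), Trp53inp1 1.94-fold (SE 0.05) and Ccng1 1.33-fold (SE 0.03).

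Cell-cycle genes were lower. Of 22 G2/M genes, 19 fell and 0 rose (median −0.36, camera adjusted p = 1.6e-08, and adjusted p = 0.114 with an estimated correlation). The spindle checkpoint genes Bub1b and Bub1 fell 1.59-fold (SE 0.03) and 1.55-fold (SE 0.04), Kif20a 1.55-fold (SE 0.03) and Tpx2 1.54-fold (SE 0.03). Of the 19 that fell, 6 lie on chromosome 2, whose genes were lower in general. Among the 14 members off chromosomes 2, 3, 5 and 12 the median was −0.32 (camera adjusted p = 1.9e-05). Of 24 DNA replication and G1/S genes, 18 fell and 0 rose (median −0.18, camera adjusted p = 1.4e-04, and adjusted p = 0.155 with an estimated correlation). Rfc4 fell 1.67-fold (SE 0.07), the sliding clamp gene Pcna 1.47-fold (SE 0.03), Mcm4 1.37-fold (SE 0.03) and Mcm5 1.35-fold (SE 0.03).

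Most heat shock and antioxidant genes were slightly lower. Of 14 heat shock genes, 11 fell and 1 rose (median −0.21 but mean −0.03, camera adjusted p = 0.0028, and adjusted p = 0.317 with an estimated correlation). Hspa1b fell 1.52-fold (SE 0.08), the collagen chaperone gene Serpinh1 1.36-fold (SE 0.03), and Hspa8 and Hspd1 each 1.20-fold (SE 0.03). Of 13 NRF2 target genes, 10 fell and 2 rose (median −0.25, camera adjusted p = 0.0080, and adjusted p = 0.197 with an estimated correlation). Gsta4 fell 1.95-fold (SE 0.05), Gsr and Nqo1 each 1.31-fold (SE 0.04) and G6pdx 1.22-fold (SE 0.03).

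Factors of 3′-end cleavage and polyadenylation went both ways, with 11 higher and 6 lower of 25 (median 0.03, camera adjusted p = 0.558). The torpedo exonuclease gene Xrn2 fell 1.49-fold (SE 0.03), from 308 ± 16.5 to 206.3 ± 5.25 CPM, and Cstf1 1.48-fold (SE 0.05), while Pcf11 rose 1.32-fold (SE 0.04) and Fip1l1 1.30-fold (SE 0.03). Cpsf3, which encodes CPSF73, rose 1.24-fold (SE 0.04), from 56.9 ± 1.6 to 70.7 ± 2.4 CPM, and its scaffold gene Sympk 1.19-fold (SE 0.03). Of this list's 6 falling members, 4 lie on chromosome 2, whose genes were lower in general, and 4 of its 11 rising members, Cpsf3 and Fip1l1 among them, lie on chromosomes 5 and 12, whose genes were higher in general. Integrator subunits had 5 members higher and 3 lower of 14 (median 0.002, camera adjusted p = 0.565), with Ints3 1.32-fold higher, Ints5 1.24-fold higher, Ints1 1.20-fold higher and Ints6 1.26-fold lower. Of the 5 rising Integrator members, 3 lie on chromosomes 3 and 5, whose genes were higher in general, and off chromosomes 2, 3, 5 and 12 the list median was −0.055. Histone pre-mRNA processing factors had 2 higher and 4 lower of 12 (median −0.09, camera adjusted p = 0.785), among them Eri1 (log2 −0.32) and Casp8ap2 (log2 −0.14). Replication-dependent histone genes had 9 higher and 17 lower of 55 (median −0.05, camera adjusted p = 0.558). Hist1h4i rose 1.63-fold and Hist2h4 1.37-fold, and Hist1h2bp fell 1.76-fold and Hist1h2an 1.37-fold. These histone genes are near-identical copies, so the split of reads between them is uncertain. Of 13 ubiquitin ligases and CPSF73 partners of UBE3D, 4 rose and 7 fell, with Ube2cbp itself among the latter (median −0.07, camera adjusted p = 0.558). Ube2c fell 1.57-fold, Anapc1 1.40-fold, and Ube3c rose by 0.32 on the log2 scale. Of these members, 3 of the 4 that rose lie on chromosomes 5 and 12, and 3 of the 7 that fell, Ube2c and Anapc1 among them, on chromosome 2.

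**Figure D3:**
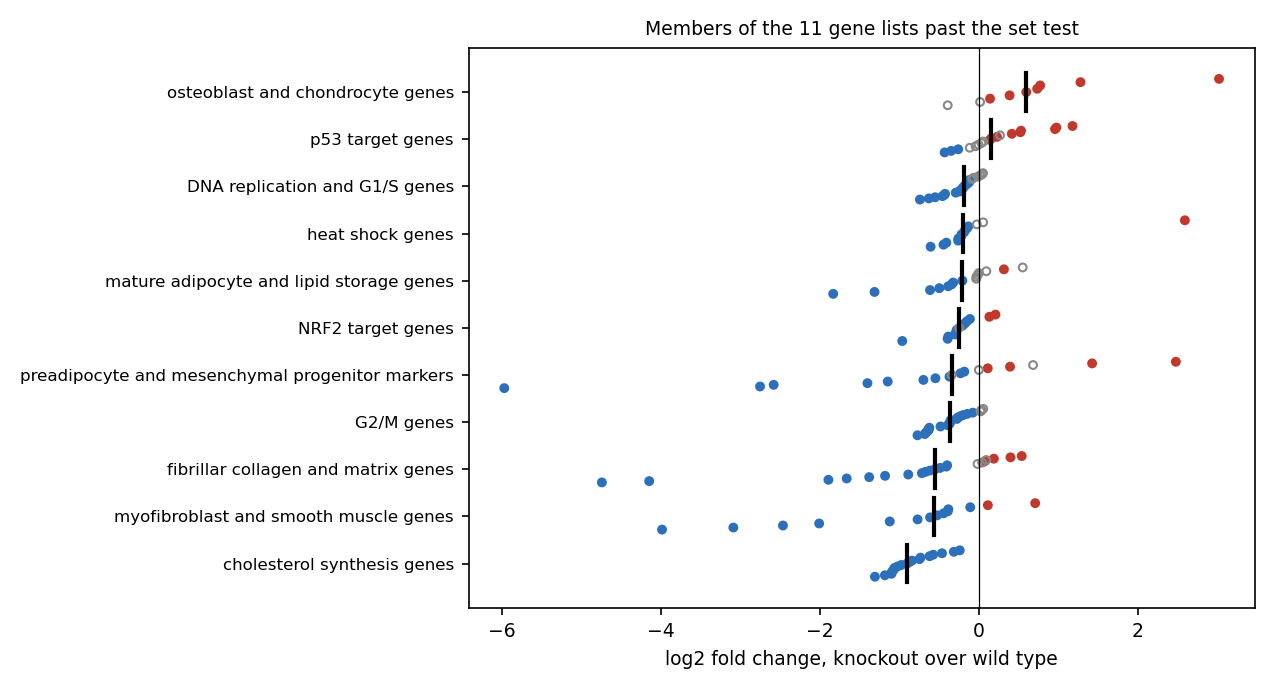
Log2 fold change (knockout over wild type) of each tested member of the 11 gene lists past the set test. Filled points passed the gene-level threshold (red higher, blue lower), open points did not, and black bars are the list medians, from −0.90 for cholesterol synthesis to 0.60 for osteoblast and chondrocyte genes.

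Camera with a preset correlation of 0.01 called 11 of the 31 testable lists, 2 higher and 9 lower. With an estimated correlation it called 0, while 7 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 21. With the preset correlation, the other splits of the 6 libraries into 3 and 3, which mix the genotypes, called between 2 and 11 lists. Each of these splits holds unequal numbers of knockout libraries in its 2 groups, so that a part of the genotype difference remains. They therefore cannot show how many lists would be called without a genotype effect. The list calls hold only at the setting with the preset correlation, which also has more degrees of freedom, and stay uncertain. Adjusted over the list alone, the counts of rising and falling members were those given above in 25 lists. They differed in inhibitors of adipogenesis (8 higher, 5 lower, adjusted over the list alone), replication-dependent histones (8 and 16), hypoxia and glycolysis (3 and 8), ribosomal proteins (11 and 23), nuclear RNAs (1 and 2) and macrophage markers (2 and 2).

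Gene counts were distributed unevenly over the chromosomes. On chromosome 3, 450 of 643 tested genes were higher and 60 lower (median log2 0.30), on chromosome 5, 467 of 804 were higher and 86 lower (median 0.19), and on chromosome 12, 244 of 447 were higher and 52 lower (median 0.19). On chromosome 2, 598 of 1023 tested genes were lower and 160 higher (median −0.24). The median over all tested genes was 0.004. Off these 4 chromosomes, 5838 of 10030 genes were called (58.2%), 2597 higher and 3241 lower, and on them 2117 of 2917 (72.6%). A separate fit of the 10030 genes alone called 2576 higher and 3227 lower. The 4 chromosomes were singled out after the data were seen, by a median of at least 0.15 in either direction.

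**Figure D4:**
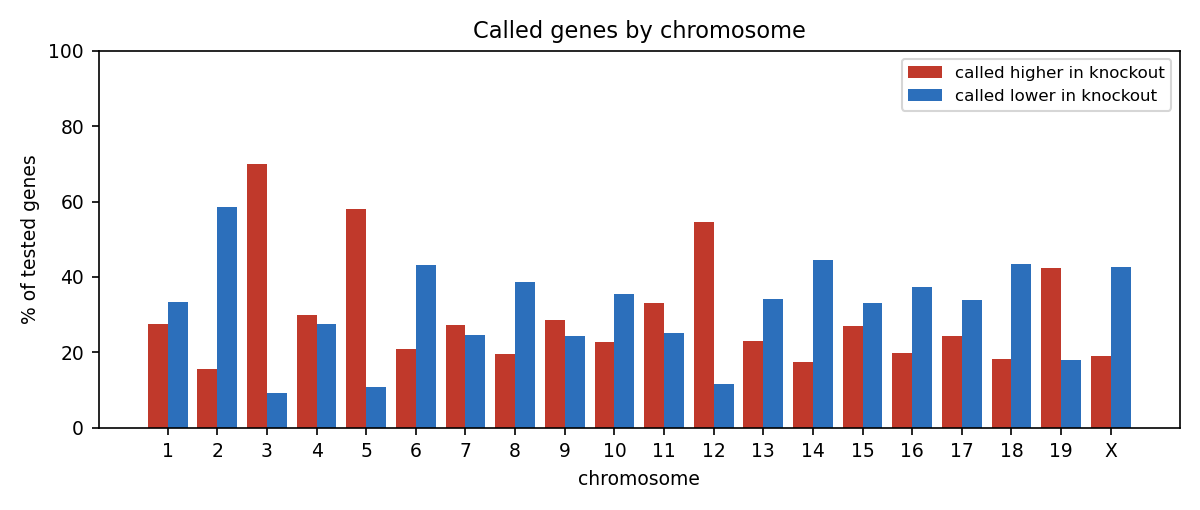
Percent of tested genes called higher (red) and lower (blue) in the knockout on each chromosome. Chromosome 2 has 160 higher and 598 lower of 1023 tested genes, and chromosome 3 has 450 higher and 60 lower of 643.

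A separate set of counts addresses readthrough, that is, transcription that runs on past the 3′ end of a gene. Downstream-of-gene (DoG) regions had higher counts in the knockout. Of 1670 tested regions, 1270 (76.0%) were higher, 88 were lower and 312 were not called (edgeR, adjusted p under 0.05). The median log2 change was 0.77, or 1.71-fold, with a 5th to 95th percentile range of −0.20 to 1.80, against a median of 0.004 for genes. At least a doubling was seen for 569 regions and at least a halving for 15. Every knockout library lay above every wild-type library in 1274 regions (76.3%, where chance gives 5% for regions chosen without regard to these libraries), and below in 88. How the regions were chosen is not given in the sources used here. A choice that favoured regions with knockout reads would raise this share. The median level per library was 5.44 ± 0.22 CPM in the knockout and 3.04 ± 0.29 CPM in wild type, a ratio of 1.79 (exact permutation p = 0.1, the smallest that 3 libraries against 3 allow). DoG counts amounted to 3.04% ± 0.10 of gene counts in the knockout and 2.51% ± 0.08 in wild type (exact permutation p = 0.1).

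The rise was larger in regions of low count. With the regions divided by mean count into 4 bins, the median log2 changes from the lowest to the highest bin were 0.96, 0.83, 0.81 and 0.34, and the highest bin held 63 of the 88 lower regions. The regions carry no names, so that their host genes are unknown and a change in a DoG region cannot be set against its gene. The largest rises, which can only be numbered by position in the list, were those of region1358 (14.1-fold, SE 0.32), region1611 (13.4-fold, SE 0.24), region1152 (12.4-fold, SE 0.27), region765 (11.9-fold, SE 0.33), region437 (10.0-fold, SE 0.16) and region209 (8.84-fold, SE 0.17). The level of region437 went from 1.24 ± 0.22 to 12.5 ± 0.68 CPM. The largest falls were those of region1605 (log2 −5.67, SE 0.37), region1660 (34.9-fold, SE 0.17), region1600 (4.64-fold, SE 0.48), region855 (4.40-fold, SE 0.18), region1399 (4.27-fold, SE 0.33) and region1284 (3.56-fold, SE 0.08). Of the most abundant regions, region1629, with 9.16% of all DoG counts, changed by −0.07 on the log2 scale (SE 0.03, edgeR adjusted p = 0.023), and region307, with 8.88%, rose by 0.41 (SE 0.03).

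The direction rests on scaling by the gene counts of the same libraries. Scaled by the DoG totals instead, which removes any change common to the regions, 483 regions were higher and 436 lower (median 0.06), so that 52.6% of the called regions were higher against 93.5% with the gene counts.

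**Figure D5:**
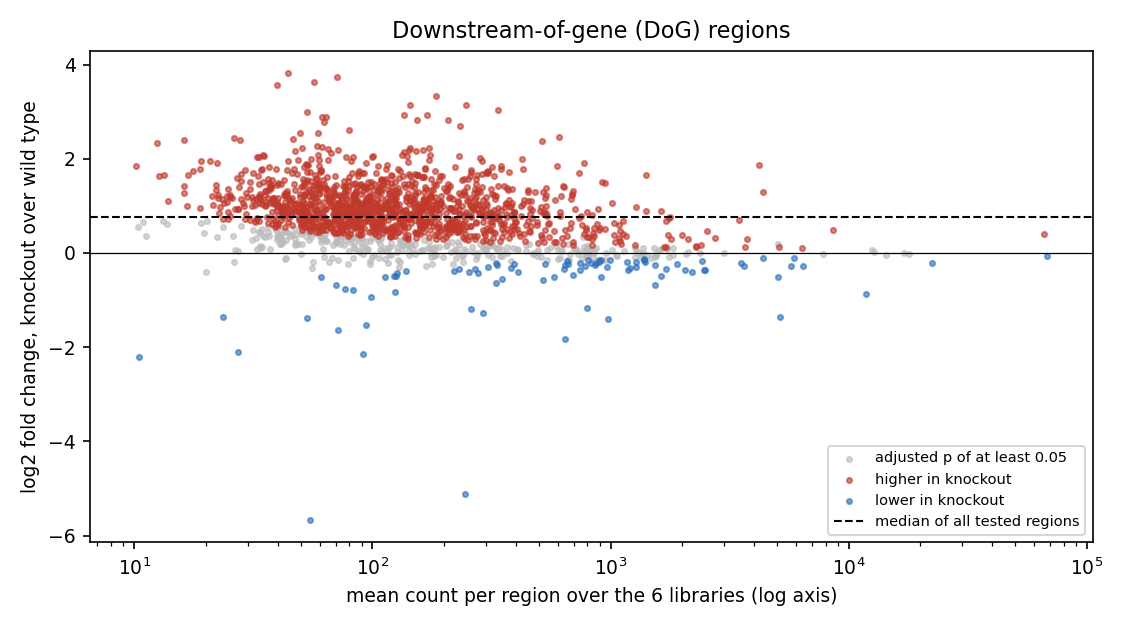
Log2 fold change (knockout over wild type) of the 1670 tested DoG regions against their mean count over the 6 libraries on a log axis. Red points are the 1270 regions called higher and blue points the 88 called lower, and the dashed line is the median of 0.77.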

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

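Leaving out Rn45s and leaving out chromosomes 2, 3, 5 and 12 were chosen after the data were seen, and the other alternatives before. No called gene was called in the opposite direction under any setting. Of 1942 values for 142 named genes, 1931 kept their direction and side of the threshold and 11 no longer passed it (Rn45s, Rmrp and Lyz2 under some settings). The count of genes higher was 2576 without the 4 chromosomes, where fewer genes were tested, and the count at least doubled was 348 with a filter at 1 CPM, which removes low genes. DESeq2 called 3418 genes higher and 3609 lower, and 937 of the 7955 calls were lost; limma-voom called 3869 and 4018; leaving out a library lost 619 to 785. With the DoG totals as library sizes 483 regions were higher and 436 lower (median 0.063), since that scaling removes a common change; under the other settings the median lay between 0.73 and 0.83. With an estimated correlation 0 lists were called higher and 0 lower. The size of the correlation does not account for all of this loss. For the mature adipocyte list the estimate was 0.0103, near the preset 0.01, yet the unadjusted camera p went from 0.0023 to 0.038. For the preadipocyte list the estimate was −0.014, and its call was lost as well. The 2 settings also differ in the degrees of freedom of the camera test. With an estimated correlation these come from the few libraries, and with a preset one from the number of genes. The loss of calls therefore cannot be read as an effect of correlation between genes alone. The preadipocyte list had a camera adjusted p of 0.0502 to 0.341 where its call was lost. For histone genes the median ranged from −0.10 to 0.0030 when single libraries were left out, turning positive without wild-type replicate 1. Off the 4 chromosomes the Integrator median was −0.055, and the camera direction turned for the TGF-beta (median 0.15) and stress response (0.042) lists; the cause was not tested. Same-numbered libraries deviated from their group means with a correlation of −0.03 for each pair, and the other pairs lay between 0.009 and 0.022. No positive shared effect of the replicate number was therefore seen. Such correlations cannot show whether same-numbered cultures were handled together. With the replicate block 3844 genes were higher and 4078 lower, 1249 DoG regions higher and 75 lower, and 2 lists higher and 10 lower (matrix metalloproteinases added, adjusted p = 0.044). Tests of DoG regions against host genes and of genes downstream of hosts were not run.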

Other observations

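The tests of nuclear RNA, of calls under 2-fold and of the splits were chosen after the results were seen. So were the spread of background reads, the length they would need and their ratio with genes resampled. Predictions were written beforehand for the background ratio, for Rn45s, for calls of at least 2-fold and for the read-in ratio within 10 kb. Leaving out Rn45s was itself chosen after the data were seen. Other distances, expression levels and halved genes in the read-in test had no written prediction, nor had the background ratio without its top genes. Several groups outside the main lists held large single changes. Among 14 inflammatory and NF-kB target genes, 5 rose and 7 fell (median −0.22, camera adjusted p = 0.550), with the chemokine gene Cxcl12 5.44-fold lower (278 ± 1.8 to 51.1 ± 1.1 CPM), Ccl2 1.89-fold lower, Nfkbia 1.61-fold higher and Csf1 1.46-fold higher, and off chromosomes 2, 3, 5 and 12 the list median was −0.45. Of 10 Wnt target genes, 5 rose and 3 fell (median 0.33 but mean −0.15, camera direction higher with adjusted p = 0.558), with the secreted Wnt modulator gene Sfrp2 28.6-fold lower, Wisp1 1.78-fold lower, Lef1 1.73-fold higher and Ccnd1 1.31-fold higher. Imprinted growth genes divided evenly, with 4 higher and 4 lower of 8 (median 0.10, mean −0.03, camera direction lower with adjusted p = 0.834), and Peg3 fell 4.21-fold and Peg10 3.18-fold while Igf2r rose 1.42-fold. Chromosome 12 carries 2 of the rising imprinted genes, and off chromosomes 2, 3, 5 and 12 the median turned to −0.35. Of 15 interferon-stimulated genes, 2 rose and 6 fell (median −0.22, camera adjusted p = 0.401), with Stat2 2.35-fold lower. Of 19 HOX genes, 0 rose and 9 fell (median −0.14, also with Hoxb6 at its bound, camera adjusted p = 0.193), and Hoxb6 had 0 counts in the knockout, at least 3.88-fold lower than in wild type against a floor of 3 counts per library.

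Stress response genes had 6 higher and 8 lower of 20 (median 0.04, camera direction lower with adjusted p = 0.830), with Atf4 1.37-fold lower and Phgdh 1.29-fold higher. Hypoxia and glycolysis genes had 3 higher and 7 lower of 17 (median −0.08, camera adjusted p = 0.385), with Car9 5.38-fold higher and Hk2 1.52-fold lower. Ribosomal protein genes had 12 higher and 24 lower of 75 (median −0.03, camera adjusted p = 0.360), with Rpl35 1.38-fold lower, and without wild-type replicate 2 that list was past the threshold (camera adjusted p = 0.026). Nuclear and nonpolyadenylated RNAs had 2 higher and 2 lower of 9 (median 0.06, camera adjusted p = 0.558), with the telomerase RNA Terc higher by 0.97 on the log2 scale. Of 3 skeletal muscle genes, Tnnt2 rose 1.49-fold and Acta1 fell 2.80-fold (median −0.49, camera direction higher with adjusted p = 0.723). Macrophage and leukocyte markers had 2 higher and 1 lower of 5 (camera adjusted p = 0.785), and Fcer1g, the largest rise among them, was at 0.895 ± 0.270 CPM in the knockout and 0.160 ± 0.123 CPM in wild type. Mdm2 ranked 6 among all genes by mean level, at 4948 ± 24 CPM in the knockout and 4840 ± 169 CPM in wild type, and the adjacent Slc35e3 ranked 28, while Nup107 and Cpm beside them were below 100 CPM.

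For the DoG rise, background reads such as genomic DNA, a larger share of Rn45s and more nuclear RNA in the knockout libraries were considered. A larger Rn45s share would enlarge the knockout library sizes and so lower DoG values there, which is opposite to the rise. Leaving Rn45s out of the library sizes gave a median DoG change of 0.78, an outcome that this direction largely fixed. The 9 tested nuclear and nonpolyadenylated RNAs had a median of 0.057 with an SD of 0.51, below the DoG median of 0.77. They did not rise together by that amount. However, Terc rose by 0.97 and Rn45s by 0.31 on the log2 scale, 2 others fell, and unspliced RNA was not measured. The Rn45s counts do not tell precursor from mature ribosomal RNA. A larger share of nuclear RNA is therefore not excluded. Background stays open, since a test fixed beforehand came out as it predicts: 1547 receptor and defensin genes, chosen as silent in fibroblasts, had 1.81 times the wild-type reads in the knockout (95% interval 1.62 to 2.02 from counting error alone, 1.46 to 2.38 with genes resampled), against a median DoG rise of 1.71-fold, and 1.72 times (1.30 to 2.30 with genes resampled) without the 14 genes that held 66.4% of the reads. Against a uniform background, these reads lay in only 120 genes, where random placement by length gives 870.6, and at their density the DoG gain would need regions of 1065 kb on average (median 635 kb), where the mean extent per listed gene and strand is 222.9 kb, and of 1803 Mb in all, or 5632 Mb without the 14 genes, where both strands of the genome hold 5442 Mb, but the lengths shrink with mappability, which was not tested, and DoG lengths are not given in the sources used here, so background is not excluded. The receptor and defensin ratio does not separate background from readthrough. Readthrough into silent genes beside expressed ones could raise it as well, and such genes were not left out. More readthrough after loss of a CPSF73 partner, differences between clones and a choice of regions that favoured the knockout libraries stay open as well. The 10 splits of the 6 libraries are too few for a share under 0.05 (1358 regions in the real split, 1 split as large, highest other 0).

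The breadth of the gene changes might come in part from regional copy number or other position-linked differences between the lines. After subtracting the median of 51 neighbouring genes, 89.8% of the calls of at least 2-fold kept that size. The local medians were small, with an SD of 0.144, so broad regional shifts are too small to make up most of the large changes. A median over 51 genes cannot show a gain or loss of 1 or a few genes, so the test does not address such changes. Of 6957 calls under 2-fold, 72.9% (95% interval 71.8% to 73.9%) stayed in the same direction and at least as many SE from 0 as the weakest call, which argues against position as the cause of all of them. However, 17.5% of the tested genes lay where that local median exceeded 0.2 in either direction, against at most 0.363% in 100 shuffles of gene order, so that a position-linked part is a candidate explanation for some of them, although DNA copy number was not measured and clone and genotype cannot be separated here. For the 10 splits, which are too few for a share under 0.05, the real one gave 7955 genes (1 split as large, highest other 0) and 11 lists (2 splits as large, highest other 11).

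Genes at least doubled in the knockout may partly be reached by transcription from an upstream neighbour. Of 1408 tested genes with an expressed gene ending within 10 kb upstream on the same strand, 110 (7.81%) were at least doubled. The comparison was 55 of 1788 (3.08%) with an expressed other-strand gene starting within 10 kb upstream (odds ratio 2.67, 95% interval 1.90 to 3.79, Fisher's exact p = 2.4e-09). Of 5289 genes whose expressed upstream neighbour lay over 50 kb away, 237 (4.48%) were at least doubled. The lower limit of 1.90 is above 1, which an equal effect on neighbours of either strand does not predict. However, the 2 sets differ in more than strand, since an other-strand neighbour starts near the gene and a same-strand one ends there. The contrast therefore cannot separate read-in from a difference between such genes. Within 4 bins of expression the ratio was 2.42 (1.68 to 3.52), and within 50 kb, without bins, it was 1.86 (1.45 to 2.41). Below 5 CPM the shares were 29.1% and 12.9% (odds ratio 2.77, 1.86 to 4.17), and at or above 5 CPM, with 6 and 9 doubled genes, 0.571% and 0.628% (odds ratio 0.908, 0.27 to 2.87), too few to tell whether the ratios differed, and genes at least halved were also more frequent beside same-strand neighbours (odds ratio 2.29, 1.14 to 4.78), which a read-in does not explain. An example, chosen after its values were seen, is Nlgn3, 0.245 kb after Med12, whose log2 change was 2.80 (SE 0.36) while that of Med12 was −0.04 (SE 0.04).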
